A study of Mus musculus with 6 samples.

How the data were processed

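Small RNA was sequenced from the inner medulla of the kidney, the innermost zone, where collecting ducts carry urine to the renal pelvis. The samples came from 1-month-old control mice (3 libraries) and from mice lacking Dicer1 in cells that express aquaporin-2 (3 libraries, written DicerAQP2Cre+). Dicer is the RNase III enzyme that cuts most precursor miRNA hairpins into mature miRNAs, and aquaporin-2 is the water channel of collecting duct principal cells. Per the labels' protocols, total RNA was extracted with the RNeasy Micro Kit and libraries were made with the TruSeq small-RNA protocol. The series design describes separate mice, so the spread between libraries includes differences between animals. The Dicer1 transcript itself is not measured by small RNA libraries, so the deletion could not be checked in each sample.

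The deposited signal values are read counts per mature miRNA divided by 1 size factor per library. The submitters' processing notes name FastQC 0.11.3, DESeq2 and the genome build mm9; the aligner, the counting tool and the miRNA annotation release are not given in the sources used here. This unit was read from the values: each column held whole multiples of its smallest value above 0, and 100% of the values came out as whole reads within a tolerance of 0.01 read (largest deviation 0.002). Size factors recomputed from the recovered reads by the median-of-ratios method matched the deposited ones. The table held 1081 entries in 6 columns. The columns named CTR1 to CTR3 match the control titles. The columns named CK01 to CK03 were read as a short form of conditional knockout followed by the replicate number, that is, as DicerAQP2Cre+ replicates 1 to 3. This reading is an inference from the names, and every direction given here rests on it. The annotation files used here are for GRCm38, so no genome coordinates are printed, and GRCm38 annotation was used only for host genes and for neighbours within 10 kb.

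Recovered reads assigned to miRNAs ranged from 2934851 to 7614853 per library. A library in which an entry had 0 reads allows up to 3 reads, which is between 2.22 and 5.88 normalized reads depending on the library. Such floors, and 95% exact binomial intervals of shares, cover counting error only, because PCR copies are not independent molecules.

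The main test was limma (version 3.58.1, R 4.3.3) on log2(value + 1), with a mean-variance trend in the empirical Bayes step and no replicate block. All 6 libraries were used, and 461 entries with a mean value of at least 5 over all libraries were tested, leaving 620 below that filter. The tests were two-sided, and an entry was called at a Benjamini-Hochberg adjusted p under 0.05. The fit left 4 residual degrees of freedom, to which the empirical Bayes step added 6.44. Fold changes are on the log2(value + 1) scale, which understates the change of low entries. Values are normalized read counts, given as mean ± SD over 3 libraries per genotype, and log2 fold changes carry their standard error. Where mature sequences from several genes share a name or identical values, reads could be split between copies: 11 entries carried joined names and 7 pairs of tested entries had identical values, of which 0 were called.

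Before the data were examined, 22 lists of miRNAs were fixed: the miR-200, miR-30, miR-10 and miR-29 families, let-7 and miR-98, the miR-183 cluster with other epithelial miRNAs, the cortical tubule miRNAs (miR-192, miR-194 and miR-215), the miR-17~92 and miR-23/24/27 clusters, the Dlk1-Dio3 and Sfmbt2 clusters, kidney injury and fibrosis miRNAs, entries overlapping rRNA or tRNA, mirtrons and Drosha-independent miRNAs, markers of endothelial, stromal (smooth muscle, pericyte and fibroblast), leukocyte, erythroid, striated muscle and neural cells, the miRNAs followed up by the study, and miRNAs described elsewhere as acting on Aqp2. The 19 lists with at least 3 tested members were compared with all other entries by limma's camera with a preset correlation of 0.01, adjusted over lists. An estimated correlation and fry, which asks whether a list's own members move one way on balance, were run beside it. Lists overlapped: 10 entries were in at least 2 of them.

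Named miRNAs followed a rule fixed at the same time. It took the 10 lower and the 10 higher called entries with the largest fold change and no overlap between genotypes, the 5 most abundant entries, miR-451a, each arm of the miR-200 family, the miRNAs followed up by the study or described as acting on Aqp2, and from each list the 2 most abundant members and the 2 with the smallest p. Any miRNA named outside this rule was chosen after its values were seen, and is marked so. Library totals and composition were compared by exact two-sided permutation tests, where 3 against 3 libraries cannot give a p below 0.1. The fold changes of both arms of a hairpin were correlated over hairpins, with 1e+05 permutations and 1000 bootstrap draws.

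Other settings, chosen before the data were examined, were pseudocounts of 0.5 and 5, no filter and a mean filter of 50, equal library totals, TMM factors, robust or untrended empirical Bayes, edgeR's quasi-likelihood test (version 4.0.16) and DESeq2 (version 1.42.0) on the recovered reads, an adjusted p threshold of 0.1, the replicate number as a block, and leaving out each library. Chosen after the data were seen were thinning to the shallowest library, identical entries counted once, and leaving out each library in edgeR and DESeq2. The procedure was tested on simulated counts with 200 changed entries per draw, 10 draws and 456 entries tested in the first draw, for 3 against 3 libraries. It recovered 13.1% of entries changed 1.5-fold, 53.3% of those changed 2-fold and 92.4% of those changed 4-fold, and 2.56% of its calls were false. Noise was independent between entries, changes went up or down at random, and no library was made to stand apart. Both recovery and false calls depend on the share of changed entries. With a smaller share than in these draws, fewer changes would be recovered and more calls would be false. Plots were drawn with matplotlib 3.10.9.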

Results

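Mature miRNAs were measured by small RNA sequencing in the kidney inner medulla of 3 control and 3 DicerAQP2Cre+ mice at 1 month of age. Recovered reads numbered 6780624, 6205756 and 4924091 in control replicates 1 to 3, and 7614853, 2934851 and 5694159 in the DicerAQP2Cre+ replicates. Mean depth was 5970160 ± 950426 reads in controls and 5414620 ± 2352490 in DicerAQP2Cre+ samples (n = 3 each, exact two-sided permutation p = 0.8). Between 641 and 829 of 1081 entries had at least 1 read per library, with the fewest in the shallowest library. The libraries of each genotype differed by more than sampling noise, and no pair looked like a repeat of another.

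miR-181a-5p was the most abundant entry and took 48.0 ± 4.75% of reads in controls against 63.0 ± 4.36% in DicerAQP2Cre+ samples (SD, n = 3). The difference of 15.0 percentage points had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, and 0.2 after adjustment over the tests of composition. In limma miR-181a-5p had a log2 fold change of 0.61 ± 0.18 (adjusted p = 0.0641) and did not pass, whereas edgeR (adjusted p = 0.0431) and DESeq2 (adjusted p = 0.0283) called it higher. The other 4 most abundant entries, miR-125a-5p, let-7c-5p, miR-10a-5p and miR-92a-3p, did not pass either, with log2 fold changes of -0.39, 0.37, -0.65 and -0.62. The 10 most abundant entries together held 79.3 ± 0.983% of reads in controls and 83.7 ± 1.75% in DicerAQP2Cre+ samples (exact p = 0.1, adjusted 0.2).

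The first principal component, with 46.1% of the variance, separated the genotypes. DicerAQP2Cre+ replicate 3 stood apart from the other libraries on the second component, with a score of -12.5 and 23.1% of the variance. On the first component its score of 2.33 was the nearest of its group to the controls.

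**Figure D1:**
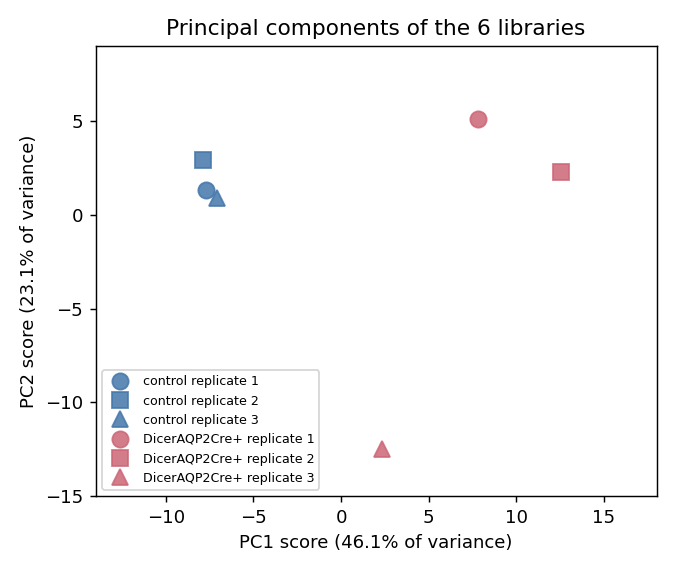
Scores of the 6 libraries on the first 2 principal components of log2(value + 1), in arbitrary units, with control libraries in blue and DicerAQP2Cre+ libraries in red. DicerAQP2Cre+ replicate 3 lies at -12.5 on the second component, apart from the other 5.

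The main comparison asked which mature miRNAs differ in the inner medulla when collecting duct principal cells lack Dicer1. Members of the miR-30 family, abundant in kidney epithelium, and of the miR-200 family, which holds epithelial cells in their differentiated state by repressing Zeb1 and Zeb2, fell. miR-30c-5p went from 14744 ± 543 to 5775 ± 577 normalized reads, 2.56-fold lower, with a log2 fold change of -1.36 ± 0.18. miR-31-5p, an epithelial miRNA, was 2.40-fold lower, but it was the 1 entry called of 8 in its epithelial list. Of those 8, 4 had a log2 fold change above 0. miR-455-3p, whose hairpin lies in an intron of the collagen gene Col27a1 in GRCm38, was 3.35-fold lower. However, control replicate 1 stood at 4947 against 14493 and 16535 in the other controls. The other arm, miR-455-5p, had a log2 fold change of -0.11 (limma adjusted p = 0.843). It lies outside the naming rule and was chosen after its values were seen. In the other direction miR-214-3p, a miRNA of stromal cells and of injured kidney, was 4.39-fold higher. Its other arm, miR-214-5p, did not pass (log2 fold change 0.50, limma adjusted p = 0.4225). That arm is outside the naming rule too and was chosen after its values were seen. miR-1247-5p, whose hairpin lies in an exon of Dio3os, was 7.34-fold higher. It had 230 normalized reads in DicerAQP2Cre+ replicate 3 against 1610 and 1773 in the others of its group.

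Of 461 entries tested, 39 passed the adjusted p threshold in limma, 23 lower (by 1.6-fold to 3.35-fold) and 16 higher (by 1.80-fold to 7.34-fold). Higher entries were thus 41.0% of calls, and 22.6% with libraries set to equal totals (14 higher, 48 lower), a scaling that moved the median log2 fold change of all entries from -0.01 to -0.21. In all 39 the control and DicerAQP2Cre+ values did not overlap. Over all tested entries 33.6% did not overlap, against 10% by chance. edgeR called 23 lower and 19 higher and DESeq2 31 lower and 29 higher, and both sets held all 39. Together the 39 called entries held 6.39% of the mean normalized reads.

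The number of calls changed strongly when 1 library was left out, which also leaves fewer samples to the test. Without control replicate 2, limma called 0 entries lower and 0 higher (43 and 40 at an unadjusted p under 0.05, edgeR 0 and 0, DESeq2 15 and 13), and without control replicate 3 again 0 and 0 (47 and 45 unadjusted, edgeR 0 and 0, DESeq2 20 and 17). Counts of lower and higher calls were 11 and 8 without control replicate 1, 31 and 10 without DicerAQP2Cre+ replicate 1, 10 and 5 without DicerAQP2Cre+ replicate 2, and 62 and 43 without DicerAQP2Cre+ replicate 3.

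**Figure D2:**
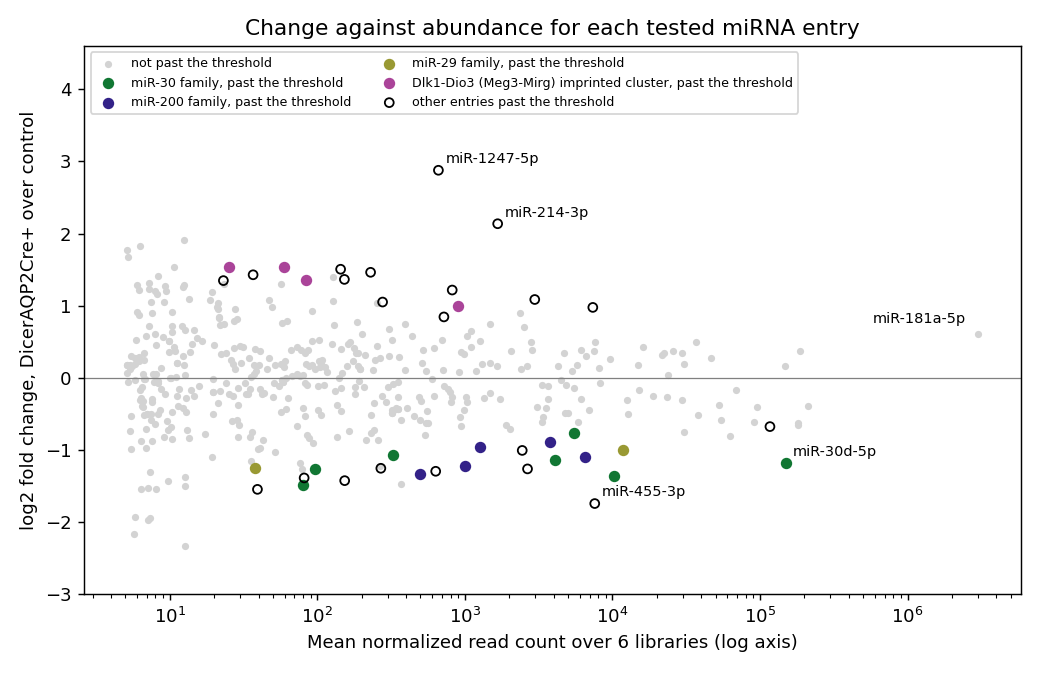
Log2 fold change (DicerAQP2Cre+ over control) of each of the 461 tested entries against its mean normalized read count on a log axis, with called entries coloured by list or drawn as open circles. miR-1247-5p and miR-214-3p lie highest among the called entries at 2.88 and 2.14, and miR-455-3p lies lowest at -1.74.

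All 11 tested miR-30 entries had lower means in DicerAQP2Cre+ samples. In limma 7 of them fell over all entries tested, and 10 were lower when adjusted over the list alone. miR-30d-5p, the most abundant member, went from 205437 ± 20036 to 94036 ± 35444 normalized reads (log2 fold change -1.19 ± 0.25, limma adjusted p = 0.0162), and miR-30e-5p from 5646 ± 395 to 2550 ± 140 (-1.15 ± 0.18, adjusted p = 0.0126). In DicerAQP2Cre+ replicate 3, miR-30d-5p stood at 134760, above the 70127 and 77222 of the other libraries of its group. The passenger arms miR-30d-3p and miR-30b-3p also fell, by 1.48 and 1.26 on the log2 scale. miR-30a-5p did not pass (-0.80 ± 0.30, adjusted p = 0.118), with 72443 in DicerAQP2Cre+ replicate 3. In GRCm38 Mir30b and Mir30d are neighbours, and Mir30c-1 and Mir30e lie in introns of Nfyc.

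All 8 tested miR-200 family entries had lower means, of which 5 fell over all entries tested and 8 were lower when adjusted over the list alone. These 5 were the 3p arms of each member. miR-141-3p went from 703 ± 70.8 to 292 ± 118 (log2 fold change -1.33 ± 0.29, limma adjusted p = 0.0169) and miR-429-3p from 1401 ± 59.0 to 604 ± 109 (-1.23 ± 0.21, adjusted p = 0.0126). miR-200b-3p, the most abundant, went from 8698 ± 172 to 4236 ± 1625 (-1.10 ± 0.25, adjusted p = 0.0188), with 6108 in DicerAQP2Cre+ replicate 3 against 3399 and 3200. miR-200a-3p and miR-200c-3p fell by 0.96 and 0.90. The 5p arms of miR-141, miR-200a and miR-200b had log2 fold changes of -0.83, -0.72 and -0.58 and did not pass over all entries. Mir200a, Mir200b and Mir429 lie in an intron of Ttll10 in GRCm38, and Mir200c and Mir141 are neighbours elsewhere.

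The miR-29 family, which represses collagen and other matrix genes, had 6 tested entries with lower means. Of these 2 fell over all entries tested and 4 were lower when adjusted over the list alone. miR-29a-3p went from 15781 ± 934 to 7925 ± 1154 normalized reads (log2 fold change -1.0 ± 0.19, limma adjusted p = 0.0136). miR-29b-2-5p fell by 1.25.

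**Figure D3:**
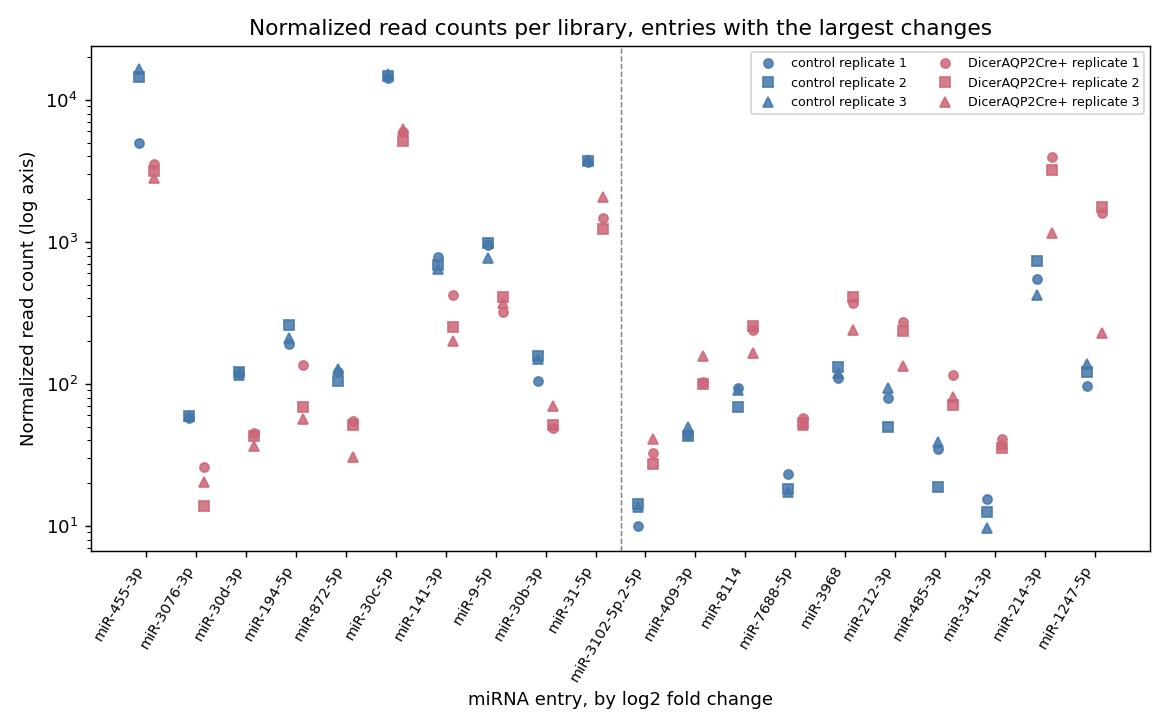
Normalized read counts per library on a log axis for the 10 lower (left of the dashed line) and 10 higher miRNAs with the largest fold changes, with control libraries in blue, DicerAQP2Cre+ libraries in red and a symbol for each replicate number. miR-30c-5p lies at 14172 to 15251 in the controls and at 5138 to 6262 in the DicerAQP2Cre+ libraries, and miR-214-3p at 422 to 735 and at 1155 to 3941.

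Of the 19 lists tested, 6 differed by camera, 3 lower and 3 higher, and 0 with an estimated correlation. The 3 higher lists include the miRNAs followed up by the study, which the study chose on these samples. That list shares miR-409-3p with the Dlk1-Dio3 list. Other splits of the 6 libraries, which each keep part of the genotype difference, gave 0 to 6 lists by the same camera test. As groups, miR-30 (median log2 fold change -1.08, camera adjusted p = 1.14e-07 in limma), miR-200 (-0.93, adjusted p = 1.03e-05) and miR-29 (-0.93, adjusted p = 0.00635) were lower than the remaining entries. None of these calls held with a correlation estimated from these libraries. The camera adjusted p was then 0.123 for miR-30 and for miR-200, and 0.152 for miR-29. For the list followed up by the study the estimate, -0.2, was below the preset 0.01. Even so its unadjusted camera p rose from 0.000261 to 0.02055. Correlation between members is thus not shown to be why the calls were lost. By fry, limma's test of each list's own members, the adjusted p was 0.00401 for miR-30 and for miR-200 and 0.00588 for miR-29.

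The Dlk1-Dio3 cluster, a large imprinted group of miRNAs expressed from the maternal chromosome, was higher in DicerAQP2Cre+ samples as a group. Its median log2 fold change was 0.91, with a camera adjusted p of 1.07e-07 in limma but adjusted p = 0.123 with an estimated correlation, and a fry adjusted p of 0.0130. Of its 29 tested entries 27 had a log2 fold change above 0, 4 rose over all entries tested and 5 were higher when adjusted over the list alone. miR-409-3p, miR-341-3p, miR-485-3p and miR-434-3p rose, by 1.35, 1.54, 1.53 and 1.0 on the log2 scale. miR-434-3p lies outside the naming rule and was chosen after its values were seen, to complete the 4. miR-341-3p went from 12.5 ± 2.85 to 37.9 ± 2.71 normalized reads (2.91-fold, limma adjusted p = 0.0162). The most abundant member, miR-127-3p, did not pass (0.37 ± 0.26, adjusted p = 0.379). In GRCm38 Mir409 and Mir485 lie in Mirg, Mir341 in an intron of Rian and Mir434 opposite Rtl1.

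Among 17 tested kidney injury and fibrosis miRNAs, miR-214-3p, miR-132-3p and miR-212-3p rose. On this count 3 were higher over all entries tested, and 6 were higher and 1 lower when adjusted over the list alone, the lower one being miR-155-5p. miR-132-3p and miR-212-3p, from neighbouring hairpins and induced by CREB in neurons, went from 483 ± 49.97 to 1157 ± 334 and from 73.9 ± 22.2 to 214 ± 71.6 (log2 fold changes 1.22 ± 0.26 and 1.5 ± 0.34, limma adjusted p = 0.0164 and 0.0174). In DicerAQP2Cre+ replicate 3 these values were lower than in the other libraries of its group: miR-214-3p stood at 1155 against 3941 and 3200, and miR-132-3p at 775 against 1394 and 1303. miR-155-5p had a log2 fold change of -1.47 ± 0.41 (limma adjusted p = 0.0512), and miR-34a-5p one of -0.61 (adjusted p = 0.137). The list had a median of 0.50 and a camera adjusted p of 0.0144 in limma, and adjusted p = 0.400 with an estimated correlation. Its call was also lost with a mean filter of 50 (adjusted p = 0.0944), without DicerAQP2Cre+ replicate 1 (0.0690) and without DicerAQP2Cre+ replicate 2 (0.0667), and its fry adjusted p was 0.153.

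miR-7688-5p, miR-8114 and miR-409-3p, the miRNAs followed up by the study, all rose, 3 of 3 over all entries tested and 3 of 3 adjusted over the list alone. miR-7688-5p went from 19.5 ± 3.09 to 53.9 ± 3.42 normalized reads (log2 fold change 1.43 ± 0.28, limma adjusted p = 0.0148), miR-8114 from 84.3 ± 13.3 to 221 ± 49.4 (1.36 ± 0.27, adjusted p = 0.0148) and miR-409-3p from 45.7 ± 3.21 to 121 ± 32.7 (1.35 ± 0.27, adjusted p = 0.0148). The list was chosen by the study on these samples, so its count is not independent evidence. Its camera adjusted p was 0.00124 in limma, with adjusted p = 0.123 with an estimated correlation, and its fry adjusted p was 0.00124. Of the miRNAs described elsewhere as acting on Aqp2, miR-32-5p was below the filter, at 1.16 ± 0.67 normalized reads in controls and 0.65 ± 1.13 in DicerAQP2Cre+ samples, too few to show a difference at this depth.

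Markers of other cell types were compared in the same way. Of 15 stromal entries miR-214-3p and miR-145a-5p rose (2 higher over all entries; 3 higher and 1 lower adjusted over the list alone), miR-145a-5p from 1925 ± 564 to 4024 ± 764 normalized reads (limma adjusted p = 0.0196), while miR-143-3p had a log2 fold change of 0.31 ± 0.19 and did not pass. No entry passed among 13 leukocyte entries (1 higher and 1 lower adjusted over the list alone), the list that holds miR-181a-5p. The 2 endothelial entries, miR-126a-3p and miR-126a-5p, had log2 fold changes of -0.15 and -0.25. miR-451a, an erythroid miRNA that matures without Dicer, stood at 23.8 ± 7.23 and 18.7 ± 7.07 (-0.35 ± 0.39, limma adjusted p = 0.605), and none of the 4 erythroid entries passed (0 adjusted over the list alone). miR-133a-3p was the 1 striated muscle entry tested (-0.15). Of 8 neural entries miR-132-3p and miR-212-3p rose and miR-9-5p fell by 1.3 (3 higher and 1 lower adjusted over the list alone). Camera adjusted p values in limma were 0.134 for the stromal and leukocyte lists, 0.553 for the erythroid and 0.229 for the neural list.

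Of the remaining lists, the miR-183 cluster with other epithelial miRNAs had 1 of 8 entries lower, miR-31-5p, which went from 3725 ± 61.1 to 1588 ± 425 (1 adjusted over the list alone). Log2 fold changes were below 0 for 4 of these entries and above 0 for 4, the latter including miR-205-5p (0.42) and miR-182-5p (0.18). The 3 entries of the cortical tubule list included 1 lower, miR-194-5p, at 220 ± 34.2 and 86.7 ± 42.6 (1 adjusted over the list alone). No entry passed among 4 miR-10 family entries (2 lower adjusted over the list alone) or among 17 let-7 and miR-98, 14 miR-17~92, 11 miR-23/24/27 and 21 Sfmbt2 cluster entries (0 each adjusted over the list alone). The Sfmbt2 list had a median log2 fold change of 0.16 but a mean of -0.05. Among entries overlapping rRNA or tRNA 1 of 4 rose, miR-3968, and among mirtrons and Drosha-independent miRNAs 1 of 14, miR-3102-5p.2-5p (1 each adjusted over the list alone). In the order named, camera adjusted p values in limma were 0.529, 0.0917, 0.0731, 0.175, 0.414, 0.414, 0.858, 0.414 and 0.0917, all above the threshold. The miR-10 list was called without DicerAQP2Cre+ replicate 3 (limma camera adjusted p = 0.000943), in which miR-10a-5p stood at 244510 against 98586 and 105200, without control replicate 2 (0.0338), with no filter (0.00230) and, in a setting chosen after the data were seen, with all libraries thinned to the shallowest (0.0295). The stromal list was called without DicerAQP2Cre+ replicate 3 (0.0366) and with no filter (0.00656), the mirtron list without control replicate 1 (0.0457), and the cortical tubule list with no filter (0.0171). By fry the cortical tubule list alone among these passed, with an adjusted p of 0.00401.

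**Figure D4:**
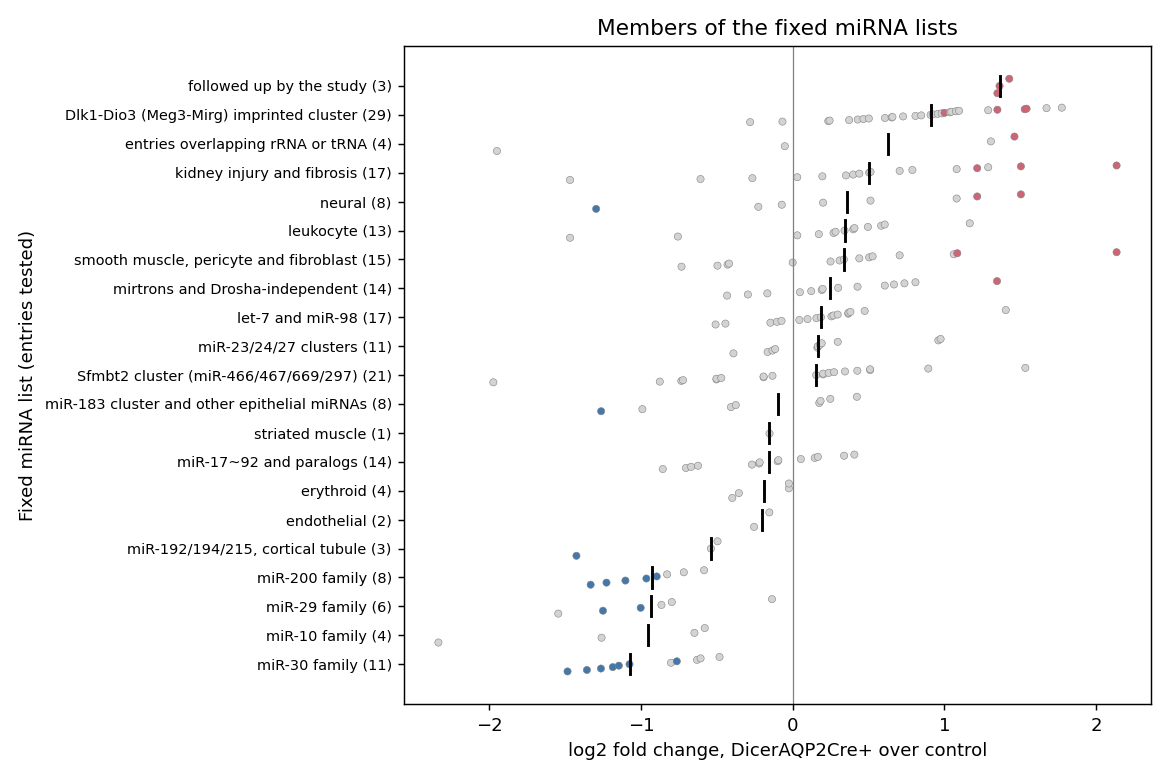
Log2 fold changes (DicerAQP2Cre+ over control) of the tested members of each fixed list, 1 point per entry, blue where it fell, red where it rose and grey where it did not pass, with a black line at the list's median. The miR-30, miR-200 and miR-29 members lie below 0 throughout, and 27 of the 29 Dlk1-Dio3 members lie above 0.

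Arms were matched by name, which leaves out hairpins whose arms carry different names, such as that of miR-30c-5p and miR-30c-1-3p, which both fell (miR-30c-1-3p, outside the naming rule, was chosen after its values were seen). Among the matched hairpins miR-30b and miR-30d were the 2 in which both arms fell, and 0 had arms called in opposite directions. In 17 matched hairpins 1 arm passed and the other did not, and in 16 of these the other arm had a fold change of the same sign. Over the 112 matched hairpins with both arms tested, the arms' log2 fold changes had a Spearman correlation of 0.475 (bootstrap SD 0.0825) and a Pearson correlation of 0.394, with a permutation p of 1e-05, the smallest that the permutations could give. This correlation is across genes within the same libraries, and hairpins are not independent replicates.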

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

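Thinning to the shallowest library, counting identical entries once, and leaving out libraries in edgeR and DESeq2 were tests chosen after the result was seen; the others were planned. All 39 called entries kept their sign in every alternative that tested them (34 with the mean filter of 50). Against 23 lower and 16 higher entries, the lower count was 48 with equal totals, 11 without a trend and 41 at a threshold of 0.1, and the higher count was 7 without a trend, 29 by DESeq2 and 30 at a threshold of 0.1. Leaving out 1 library gave 0 to 62 lower and 0 to 43 higher entries in limma, with 0 without control replicate 2 or 3 (smallest adjusted p 0.0742 and 0.0623) and the highest counts without DicerAQP2Cre+ replicate 3. edgeR's lower counts were 12 without control replicate 1, 0 without control replicate 2 or 3, 8 without DicerAQP2Cre+ replicate 2 and 52 without DicerAQP2Cre+ replicate 3; its higher counts were 0 without control replicate 2 or 3, and 10 and 66 without those DicerAQP2Cre+ libraries. DESeq2 gave 15 lower without control replicate 2, and 55 lower and 46 higher without DicerAQP2Cre+ replicate 3. Fewer samples are left in these fits; why these libraries matter most was not tested. Of 6 lists called, 3 were with the mean filter of 50, which left the miR-29 list and the list followed up by the study with too few members to test, and 0 with an estimated correlation. The correlation between arms was 0.577 with the mean filter of 50 and 0.320 to 0.524 with 1 library left out, lowest without DicerAQP2Cre+ replicate 1.

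The replicate number as a block gave 18 lower and 14 higher entries and 7 lists, the miR-10 family being the added one (adjusted p 0.0320). Deviations of samples with the same number correlated at -0.0589, 0.00541 and 0.0551, and not every sample correlated best with its own number. These values give no sign that the numbers pair the samples. They cannot exclude it, since the deviations come from means of only 3 libraries.

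Values that changed sign did not pass the test before or after, and the cause was not tested. With equal totals miR-182-5p was at -0.0282 and let-7b-5p at -0.0554. miR-2137 and miR-486b-3p turned positive with TMM (0.0064 and 0.0326), edgeR (0.287 and 0.0693) and DESeq2 (0.265 and 0.0557). The median of the miR-183 list was 0.25 after thinning, and that of the Sfmbt2 list -0.0226 with no filter. With 1 library left out, the ranges were -0.30 to 0.0602 for the erythroid list, -0.10 to 0.24 for the Sfmbt2 list, -0.418 to 0.0293 for miR-126a-3p, -0.384 to 0.0516 for miR-467d-5p, -0.33 to 0.15 for miR-133a-3p, -0.50 to 0.73 for miR-2137 and -0.22 to 0.20 for miR-486b-3p. Depth limits entries near the filter: a mean of 5 is about 2.55 reads in the shallowest library.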

Other observations

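The tests of other splits of the libraries by entries, of scaling, of a mixture in DicerAQP2Cre+ replicate 3, of each DicerAQP2Cre+ library's shift when held out and of major against minor arms were chosen after the result was seen, and every miRNA named in this part was chosen after its values were seen, except miR-455-3p, miR-872-5p, miR-3076-3p, miR-1247-5p, miR-181a-5p, miR-2137 and miR-17-5p, which the naming rule gave. Of the 23 lower entries 6 were in no list. miR-26a-5p, a broadly expressed miRNA, went from 143584 ± 9055 to 89879 ± 6264 normalized reads, miR-148a-3p from 3264 ± 180 to 1629 ± 181.1 and miR-187-3p from 379 ± 35.6 to 159 ± 27.01, with log2 fold changes of -0.68, -1.01 and -1.25. Lower too were miR-872-5p (-1.39), whose hairpin lies in an intron of Ift74, miR-3076-3p (-1.55), whose hairpin overlaps an exon of Tkt, and miR-455-3p (-1.74, or -2.29 without control replicate 1). Of the 16 higher entries 4 were in no list. Besides miR-1247-5p these were miR-676-3p, from an intron of Eda, at 4956 ± 563 and 9763 ± 1266, miR-674-5p at 180 ± 28.9 and 373 ± 47.2, and miR-375-3p, best known from pancreatic islets, at 518 ± 89.9 and 923 ± 74.5.

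Mir1247 lies in Dio3os, at an end of the Dlk1-Dio3 domain, and was not part of the list for that cluster. The 44 members of the cluster below the filter were not tested: 27 had a higher and 17 a lower mean in DicerAQP2Cre+ samples. Among the lower, miR-379-5p stood at 4.77 ± 2.1 normalized reads in controls and 3.38 ± 4.27 in DicerAQP2Cre+ samples and miR-411-3p at 2.0 ± 0.779 and 1.67 ± 1.55. Among the higher, miR-666-3p stood at 1.1 ± 0.418 and 5.95 ± 1.88 and miR-127-5p at 1.1 ± 0.392 and 7.03 ± 3.78. miR-770-3p had 0 reads in the 3 controls, which allows up to 2.31 to 2.90 normalized reads per library, and 3.07 ± 0.85 in DicerAQP2Cre+ samples.

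The higher entries are a pattern to weigh, since loss of Dicer removes mature miRNAs. With libraries set to equal totals 14 of the 16 were called higher again. That is another relative scaling, and miR-181a-5p makes up much of each total. It therefore cannot show whether these miRNAs rose in absolute amount or only relative to a lowered total. A smaller share of epithelium was predicted to raise markers of every other cell type alike. The leukocyte list changed by 0.399 ± 0.126 (SE) more than the endothelial list on the log2 scale (exact permutation p = 0.1, the smallest possible). The stromal list changed by 0.556 ± 0.271 more (exact permutation p = 0.2), only just past 2 SE. These contrasts cannot decide, since other cell types need not rise equally. The endothelial value also rests on 2 arms of 1 hairpin, and the leukocyte list holds miR-181a-5p, so it may not track leukocytes. A change in stromal cells, whose list moved by 0.352 ± 0.139 (exact p = 0.1), stays open as a hypothesis. The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 23 lower and 16 higher entries and the highest other gave 0 of either, so 1 split reached each count. By contrast 2 splits reached 6 lists, the other one setting control replicates 1 and 3 with DicerAQP2Cre+ replicate 3 against the rest. The other splits called between 0 and 6 lists by camera with the preset correlation, although each called 0 entries. Each of them mixed the genotypes unequally, so part of the genotype difference remained in it. Their counts therefore cannot show how often this test calls a list without such a difference. A list called by that test alone stays weak evidence, since 0 lists were called with an estimated correlation.

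DicerAQP2Cre+ replicate 3 stood apart from the other libraries of its group. By small margins it correlated better with each control (0.9732, 0.9717 and 0.9757) than with the other libraries of its group (0.9716 and 0.9703). Depth is argued against, since after thinning its mean correlation with them was still lower than their own, with a difference of -0.0113. Over the 105 entries called without it, its shift from the control mean was at the median 0.455 of that of the others, below 0 for 19 entries and above 1 for 15, but entries chosen without a library shift less in it by selection alone: over the 105 entries with the smallest p without them, the medians were 0.759 for replicate 1 and 0.947 for replicate 2, with replicate 3 among the remaining libraries there. Over well-measured entries that did not differ between genotypes without it, its deviations had an SD of 0.570, against 0.571 for the highest of the other libraries. That library was DicerAQP2Cre+ replicate 1, and the sets of entries were unlike: 82 for replicate 3 and 125 for replicate 1. The set for replicate 1 was chosen with replicate 3 among the remaining libraries. Among the 259 well-measured entries, those with a mean of at least 50, only miR-2137, miR-17-5p and miR-874-3p lay more than 1 log2 unit outside the other 5. These were fewer than the bound of 5 set earlier, but entries with lower means were not counted. Incomplete deletion or admixed control RNA alone cannot be told apart from other differences of this mouse, because these deviations decide neither way and the deletion was not measured.

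Within the miR-30, miR-200 and miR-29 hairpins, a slower loss of the more abundant arm was weighed as a hypothesis. Over 8 hairpins with arms matched by name, the less abundant arm's log2 fold change minus that of the more abundant arm was 0.139 on average (SD 0.392), and 3 of 8 less abundant arms fell further. An exact two-sided sign-flip test over these hairpins gave p = 0.352. It cannot decide, since the hairpins are few and were measured in the same libraries. This p covers the spread between hairpins and not between mice. No biological explanation for a difference between arms was tested.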
